A study of Arabidopsis thaliana with 9 samples.

How the data were processed

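Total RNA of 2-week-old seedlings, grown on solid medium under long days, was measured in 3 genotypes with 3 biological replicates each, per the labels: Columbia (WT), se-2 and cbp20 cbp80. Per the labels' protocols, RNA was labelled with Cy3 by linear amplification and hybridised, and 1 array was scanned per sample. Per the file headers, the scanner software was Agilent Feature Extraction 10.5.1.1 for WT replicates 1 and 2 and 10.7.3.1 for the other arrays. The software's protocol for WT replicate 3 differed from that for the other arrays. The file headers also place the 6 mutant arrays on 1 slide with 1 scan and the 3 WT arrays on 3 further slides, so there were 4 slides.

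The deposited scanner files hold an intensity per spot. Per the file headers, the processed signal had its background subtracted and was detrended within the array, and nothing was normalized between arrays. The deposited value table of the authors holds log2 values: each column ranked the probes as the processed signal did (rank correlation 1), with column medians of 0.322 to 0.323 and highest values of 17.5 to 17.9. Its log2 scale and quantile-like shape were read from the values and are not stated in the headers, and its centring stays unknown. The share of probes at a column's minimum equalled the share of signals at or under 1 (17.0% to 28.6%), except for cbp20 cbp80 replicate 3 (0.00666% against 0%). That table was used as an alternative.

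From the scanner files, control spots and spots marked as outliers (0 to 39 per array) were left out. No spot was saturated. As most probes were not well above background, each array's log2 processed signal was reduced by its 75th percentile over the 1835 probes well above background on all 9 arrays. Tested were the 3103 probes well above background on all 3 arrays of at least 1 genotype, with 23 values missing. All 9 arrays entered 1 fit with a mean per genotype by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and a probe was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. A moderated F-test compared the 3 genotypes. A transcript with several probes was represented by its brightest probe. A probe not well above background on 1 or more arrays of the dimmer genotype has only a bound there. Its fold was taken from the brighter group's mean to the dimmer group's mean, with each dim array at the higher of its lowest signal well above background and the probe's own signal, and is written as "at least". In medians, only transcripts well above background on no array of a genotype were set at their bounds, and a bound that allowed no change counted as 0.

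The slide was fitted as a random block (duplicateCorrelation, consensus 0.948) for each mutant against WT. The mutants were compared also within their slide, in a fit of its 6 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

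Probe names gave 10459 probes with TU names, 2786 with TU names and coordinates whose genome build the files do not give, 331 probes of miRNA precursors, 1428 of named loci and 9 of promoter probes. Of the locus probes, 1404 were found in the reference gene table (assembly TAIR10.1), which gave symbols, classes and neighbours and no coordinates. A symbol was available for 1718 probes and for none of 13295 others. Precursor symbols are the file's names without the species prefix.

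Gene lists were fixed before the data were examined, as were the main test, the alternatives and the rule for named transcripts. The lists were the mutated genes, MIR genes, miRNA biogenesis, small RNA silencing, exosome, TAS genes, phosphate-starvation noncoding RNAs, miRNA target genes, flowering, abscisic acid and cold response, photosynthesis and leaf, root, floral organ and housekeeping genes. The array held 0 members of the lists of mutated genes, exosome, phosphate-starvation noncoding RNAs, flowering, photosynthesis and leaf, root, floral organ and housekeeping genes. Lists with at least 3 tested members and the annotation classes were tested with limma's camera (preset correlation 0.01 and, separately, estimated) and fry, 12 sets per comparison, with Benjamini-Hochberg adjustment over these.

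Named transcripts were, for each mutant against WT, the 8 with the largest rise and the 8 with the largest fall among called probes whose mutant arrays all lay on one side of all WT arrays, and 6 further ones with a symbol. To these came the 4 in each direction between the mutants, the 5 in each direction in both mutants with the largest smaller of the changes in se-2 and cbp20 cbp80, and up to 4 members of each list.

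Alternatives were median scaling, quantile normalization, the percentile over all probes, normexp background correction (offset 50) with the same scaling or with quantile normalization, the authors' value table, no filter and a stricter filter on dim probes, the replicate number as a block, the slide as a block, a trended prior variance, array weights, the mean of a transcript's probes, only the 6 arrays of a comparison, thresholds of at least 2-fold and of an adjusted p under 0.01, and leaving out each array in turn. As the files hold no mean spot signal, normexp used the median spot signal. Array weights per genotype and the within-slide fit under other scalings were added after the data were seen, as were the medians of precursor families and the shift of the precursors under each scaling, and the splits that keep the slide of the mutants together.

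The test was tested on simulated independent arrays with 1 SD per probe, pooled over the genotypes, and 200 of 3103 probes changed between se-2 and WT. It recovered 2.09% of changes of 0.5, 38.8% of changes of 1 and 83.6% of changes of 2 on the log2 scale, and 5.06% of its calls were false. These shares do not carry over to the real arrays, which shared slides and varied more in WT. Unchanged genotypes simulated on slides that differed as the WT slides did gave 630 calls on average for se-2 against WT. The shared WT arrays were simulated 100 times. Arrays give no counts, so no counting interval was computed.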

Results

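Seedlings of Arabidopsis thaliana, 2 weeks old, were compared in 3 genotypes with 3 arrays each. The genotypes were the Columbia wild type (WT), se-2, a mutant of SERRATE, and the cbp20 cbp80 double mutant. SERRATE is a zinc finger protein that works with the Dicer enzyme DCL1 in cutting microRNA (miRNA) precursors, and CBP20 and CBP80 are the subunits of the nuclear cap-binding complex. Total RNA was labelled with Cy3 and hybridised to a one-colour array with 15013 probes for 5154 transcripts. Of these transcripts, 4499 were transcription units with TU names and no gene symbol, 224 were lncRNA loci, 145 were other ncRNA loci, 95 were protein-coding loci and 173 were miRNA precursors. No probe named SERRATE, CBP20 or CBP80, so the arrays held no check of the mutated genes.

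The probes well above background numbered 2192, 3711 and 3147 on the WT arrays of replicates 1, 2 and 3. They numbered 3404, 3286 and 3563 on the se-2 arrays and 3203, 3152 and 2809 on the cbp20 cbp80 arrays. These counts were 14.6% to 24.7% of the probes, 9107 probes were well above background on no array, and the number of arrays limits the precision. The 3103 probes of 1724 transcripts that were well above background on all 3 arrays of a genotype were tested. Each WT array lay on a slide of its own, and the 6 mutant arrays shared another slide, so every difference from WT is also a difference between slides. The correlation between arrays of a genotype, across probes, was 0.903 to 0.943 in WT, 0.994 to 0.996 in se-2 and 0.987 to 0.990 in cbp20 cbp80. The totals, the class counts and the calls of named transcripts that ended are therefore given also with the slide as a random block. That fit allows for spread between slides but cannot separate the slide of the mutants from the genotypes. It uses 1 consensus correlation for all probes and counts its degrees of freedom over arrays, so its p-values may be too small. Values are scaled log2 signals, and an error is the standard error (SE) of limma's fit with n = 3 arrays per genotype. That fit pools the spread over the genotypes, whose median SD was 0.544 in WT, 0.0856 in se-2 and 0.108 in cbp20 cbp80. Errors between the mutants therefore include the larger spread of WT. Errors and p-values of a mutant against WT can be too small where WT varied more, as for LHY, with an SD of 1.17 among WT arrays.

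The comparison of se-2 with WT addressed which noncoding transcripts of seedlings depend on SERRATE. Precursors of miRNAs were the group that stood apart: 96 of 126 tested precursors rose in se-2, 4 fell and 26 did not pass the test. Their median change was 2.81 on the log2 scale, or 7.01-fold, and 2.31 with the 25 precursors that were not well above background in one genotype set at their bounds. The precursor of MIR156c, whose miRNA targets SPL transcription factor genes, rose by 5.87 ± 0.17 (SE, n = 3), or 58.3-fold, and that of MIR168a, whose miRNA targets AGO1, rose by 5.23 ± 0.14, or 37.5-fold. That of MIR172b was not well above background on any WT array and was at least 377-fold higher in se-2. Of the 1168 transcription units 153 were higher, 220 lower and 795 did not pass, and the slide as a block left 19 higher and 11 lower. Their median change by probe was 0.014, or -0.083 with median scaling and 0.34 with quantile normalization. It became 0.96 with the percentile over all probes and -0.87 with normexp background correction, so no direction held across scalings. The percentile over all probes lies near background, as 14.6% to 24.7% of an array's probes were well above it, and normexp adds an offset of 50.

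On the list of MIR genes fixed beforehand, 36 of 38 genes were tested, by 66 probes of 37 transcripts. In se-2, 34 of these transcripts rose and 3 did not pass, and by limma 0 fell, also at an unadjusted p under 0.05. By probe, 58 were higher over all probes tested, and 60 were higher when adjusted over the list alone. The list's median change was 3.92, or 15.1-fold, also with 6 transcripts at their bounds. Further precursors that rose were those of MIR171c (5.30 ± 0.15), MIR156a (5.63 ± 0.22), MIR156d (at least 32.0-fold, well above background on 2 WT arrays) and MIR396b (at least 23.0-fold, on 1 WT array). Precursors not well above background in WT included MIR319a, at least 40.6-fold higher, MIR390b, at least 34.0-fold higher, and MIR172a, at least 20.5-fold higher. Limma's camera gave the MIR list an adjusted p of 4.36e-30 and the whole precursor class one of 7.42e-32. With an estimated correlation between probes the adjusted p of camera was 0.00038 for the list and 0.00152 for the class, so both calls held in that respect. No set test took the slide into account, so these p-values treat the arrays of the shared slide as independent. With the slide as a block, 29 of the 37 list transcripts and 68 of the 126 precursors were higher, and 1 precursor was lower.

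Among protein-coding loci, 17 rose, 20 fell and 50 did not pass in se-2, and 2 were higher and 3 lower with the slide as a block. EM1, a late embryogenesis abundant protein gene, was not well above background in WT and was at least 34.5-fold higher. LHY, a MYB transcription factor of the circadian clock, rose by 5.31 ± 0.49 (39.7-fold), and its partner CCA1 was 4.89 ± 0.86 higher with an adjusted p of 0.00253 by limma, which became 0.0588 with the slide as a block. DCL1 was the only one of 8 miRNA biogenesis genes on the array, and its brightest probe, at 0.38 ± 0.14, did not pass, with an adjusted p of 0.0655 by limma. By its 3 probes, 1 was higher over all probes tested and 2 when adjusted over the list alone. Of the 8 small RNA silencing genes 6 were measured, and by limma 0 passed by the brightest probe, also at an unadjusted p under 0.05. Of their 18 probes 3 were higher over all probes tested, 0 when adjusted over the list alone and 4 at an unadjusted p under 0.05, and RDR2 stood at -0.24 ± 0.15 and DCL2 at 0.60 ± 0.31. The locus of TAS4, AT3G25795, which gives rise to trans-acting small RNAs, was 1.23 ± 0.28 higher with an adjusted p of 0.00944 by limma (0.525 with the slide as a block). Its 2 probes were higher over all probes tested and when adjusted over the list alone.

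Of the 28 genes on the fixed list of miRNA targets, the array held 2, the auxin receptor gene TIR1, a target of miR393, and NAC1, a target of miR164. Targets outside that list were not counted. TIR1 fell by 0.74, with an adjusted p of 0.0124 by limma (0.710 with the slide as a block). NAC1, well above background on 1 WT array, stood at 1.01 ± 0.37 and did not pass, with an adjusted p of 0.0562 by limma. Its bound equalled this fitted change, and the se-2 and WT arrays overlapped, so no least rise is given. Of the 5 probes of these genes, 1 was lower over all probes tested and 1 when adjusted over the list alone. The abscisic acid and cold genes LTI65, LTI78, COR15A and KIN1, 4 of the 5 on that list, did not pass. Of their 10 probes, limma called 0 over all probes tested and 0 when adjusted over the list alone, while 2 were lower at an unadjusted p under 0.05. Their SD among WT arrays was 1.65 to 2.93. On the lists of miRNA biogenesis, small RNA silencing, TAS, miRNA target and abscisic acid and cold genes, limma with the slide as a block called 0 probes, also at an unadjusted p under 0.05.

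Among noncoding loci, 24 of 201 lncRNA loci rose in se-2, 55 fell and 122 did not pass, while 19 of 129 other ncRNA loci rose, 34 fell and 76 did not pass. The adjusted p of camera was 0.115 for the lncRNA loci and 0.0188 for the other ncRNA loci, and the latter became 0.3 with an estimated correlation. Fry, which does not compare a set with the other probes, gave adjusted p values of 0.00566 and 0.00315, both towards lower. The median changes by transcript were -0.071 and -0.27. Such a direction can move with the scaling: the percentile over all probes took the median of all probes from 0.0024 to 0.95. Fry was run under the main scaling alone and without the slide. The slide as a block left 2 lncRNA loci higher and 3 lower, and 3 other ncRNA loci higher and 4 lower. The lncRNA locus AT3G29644 fell by 3.14 (AT3G29644.2) and by 2.70 (AT3G29644.1). Both passed also with the slide as a block, at adjusted p values of 0.00158 and 0.00543 by limma, which does not separate slide from genotype. The lncRNA loci AT2G41178, between AT2G41170 and SIB2, and AT5G01732, between SCAR4 and AT5G01740, were not well above background in se-2. They were at least 10.9-fold and at least 5.40-fold lower, with adjusted p values of 0.396 and 0.418 by limma with the slide as a block. Among transcription units, AT2TU054560 was at least 40.8-fold higher (well above background on 2 WT arrays), AT5TU075750 was at least 13.2-fold higher and AT5TU077800 fell by 4.84. AT1TU090130 was at least 23.7-fold higher, was well above background on 1 WT array and had an adjusted p of 0.237 by limma with the slide as a block. AT3TU029400, AT3TU052620 and AT5TU022680 were at least 6.84-fold, 10.4-fold and 6.50-fold lower and were not well above background in se-2. AT3TU040390 and AT5TU071970, well above background on 1 se-2 array each, were lower by at least 3.81 and 3.84 on the log2 scale. None of these 5 passed with the slide as a block, with limma's adjusted p between 0.246 and 0.625.

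In all, 1273 probes differed between se-2 and WT by limma with Benjamini-Hochberg adjustment, 624 higher and 649 lower, on 649 transcripts. With the slide as a random block, 205 probes differed, 155 higher and 50 lower, and all 205 were among the 1273. Simulated genotypes without a change, on slides that differed as much as the WT slides did, gave 630 calls on average (519 to 715) over 9 arrays and 7.77 (0 to 24) with the slide as a block. The split moved with the scaling: the percentile over all probes gave 1762 higher and 177 lower, normexp background correction 274 and 2294, and the deposited values 809 and 547. Under normexp the median of the precursor probes, otherwise 2.52, was -0.0081, while it stayed above the median of the transcription units by 0.864, and MIR843, NAC1, AT5TU035150 and AT3G25795 had the opposite sign, as TIR1, RDR2 and DCL3 had with the percentile over all probes. By transcript the precursor median was 0.16 under normexp, with 56 higher and 45 lower, and 29 of the 36 precursors on the MIR list were higher and 5 lower. Normexp moved the median of all probes to -0.77, and with quantile normalization after it, which left that median at 0.037, the precursor median was 0.77, with 96 higher and 4 lower. The call of TIR1 ended without se-2 replicate 3, with an adjusted p of 0.059 by limma.

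The comparison of cbp20 cbp80 with WT addressed which of these transcripts depend on the cap-binding complex. Again the miRNA precursors stood apart: 88 of 126 rose, 4 fell and 34 did not pass, with a median change of 2.28, or 4.85-fold, and 1.93 with 28 precursors at their bounds. MIR156c rose by 5.31 ± 0.17 (SE, n = 3), or 39.7-fold, and MIR168a by 4.37 ± 0.14, or 20.7-fold. MIR156d was at least 34.5-fold higher and was well above background on 2 WT arrays. The precursor of MIR164b, whose miRNA targets NAC genes, was at least 26.0-fold higher, also with 2 WT arrays well above background. Of the 1168 transcription units 255 rose, 145 fell and 768 did not pass, and 22 were higher and 4 lower with the slide as a block. Their median change by probe was 0.27, or 0.87 with the percentile over all probes and -0.35 with normexp.

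On the list of MIR genes, 33 of 37 transcripts rose in cbp20 cbp80 and 4 did not pass, and by limma 0 fell, also at an unadjusted p under 0.05. The median change was 2.61, or 6.09-fold, and 2.58 with 7 transcripts at their bounds. Of its 66 probes 55 were higher over all probes tested, and 55 when adjusted over the list alone. MIR156a rose by 5.08 ± 0.22 and MIR156b at least 17.6-fold (well above background on 1 WT array). MIR390b, whose miRNA triggers the cutting of TAS3 transcripts, MIR395c, whose miRNA targets genes of sulfate assimilation, and MIR843 were not well above background in WT. They were at least 9.56-fold, 7.03-fold and 6.11-fold higher. MIR399c, whose miRNA targets PHO2, was at least 10.8-fold higher and was well above background on 1 WT array. MIR413 fell by 3.76, and by 2.42 in se-2. With the slide as a block its call held in cbp20 cbp80, with an adjusted p of 0.0156 by limma, and ended in se-2, with one of 0.0788. The adjusted p of camera, again without the slide, was 5.24e-18 for the list and 6.48e-17 for the precursor class, and with an estimated correlation it was 0.00169 and 0.00924, so both calls held in that respect. With the slide as a block 25 of the 37 list transcripts and 55 of the 126 precursors were higher, and 1 precursor was lower.

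The protein-coding loci split into 17 higher, 18 lower and 52 not passing, and into 2 higher and 1 lower with the slide as a block. LHY rose by 4.66 ± 0.49, and CCA1 was 4.86 ± 0.86 higher with an adjusted p of 0.00277 by limma, or 0.0687 with the slide as a block. EM1 was at least 3.65-fold higher, with an adjusted p of 0.003 by limma and 0.166 with the slide as a block. DCL1 stood at -0.33 ± 0.14 and did not pass, with 1 of its 3 probes lower over all probes tested and 1 when adjusted over the list alone. Of the small RNA silencing genes, DCL3 fell by 0.44 with an adjusted p of 0.0431 by limma (0.619 with the slide as a block). RDR2 (-0.42 ± 0.15) and NRPD1A (-0.27 ± 0.14) did not pass, and of the list's 18 probes 3 were lower over all probes tested and 2 when adjusted over the list alone. TIR1 fell by 0.59 and NAC1, well above background on 1 WT array, was at least 2.40-fold higher, and their adjusted p values with the slide as a block were 0.801 and 0.539 by limma. Of their 5 probes 1 was higher and 1 lower, both over all probes tested and when adjusted over the list alone. AT3G25795 stood at 0.33 ± 0.28, and limma called 0 of its 2 probes, also when adjusted over the list alone and at an unadjusted p under 0.05. Of the abscisic acid and cold genes limma called 0 by the brightest probe (1 at an unadjusted p under 0.05), and 1 of 10 probes was lower over all probes tested and when adjusted over the list alone. Camera gave that list an adjusted p of 0.0319, which became 0.564 with an estimated correlation. On these lists limma with the slide as a block called 0 probes, and 1 probe, of DCL1, was lower at an unadjusted p under 0.05.

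Of the 201 lncRNA loci 36 rose, 42 fell and 123 did not pass, and of the 129 other ncRNA loci 22 rose, 31 fell and 76 did not pass. The adjusted p of camera was 0.104 for the first and 0.0136 for the second, and the latter became 0.271 with an estimated correlation. By fry the adjusted p values were 0.357 and 0.0368, both towards lower, again under the main scaling alone and without the slide. The slide as a block left 3 lncRNA loci higher and 2 lower, and 2 other ncRNA loci higher and 3 lower. AT2G41178 was not well above background in cbp20 cbp80 and was at least 6.39-fold lower (adjusted p 0.373 by limma with the slide as a block). Among transcription units, AT5TU075750 was at least 23.1-fold higher, AT5TU035150 at least 11.0-fold higher (well above background on 1 WT array), and AT5TU077800 was at least 29.7-fold lower. AT3TU029400, AT5TU022680, AT4TU028510, AT3TU052620 and AT2TU062680 were not well above background in the mutant. They were at least 3.98-fold, 3.79-fold, 5.47-fold, 5.90-fold and 2.86-fold lower, and limma's adjusted p with the slide as a block was 0.323 to 0.882.

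In all, 1255 probes differed between cbp20 cbp80 and WT by limma with Benjamini-Hochberg adjustment, 748 higher and 507 lower, on 662 transcripts. With the slide as a random block, 173 probes differed, 145 higher and 28 lower. The same simulation gave 633 calls on average (531 to 716) over 9 arrays and 7.89 (0 to 23) with the slide as a block. Median scaling gave 574 higher and 722 lower, the percentile over all probes 1486 and 229, and normexp 347 and 1568. Under normexp the median of the precursor probes, otherwise 2.09, was -0.039, while it stayed above that of the transcription units by 0.313, and MIR172a, MIR319a, EM1, NAC1 and AT1TU090130 had the opposite sign, as TIR1 and DCL3 had with the percentile over all probes. By transcript the precursor median was 0.14, with 53 higher and 21 lower, and 23 of the 36 list precursors were higher and 3 lower. Normexp moved the median of all probes to -0.31, and with quantile normalization after it, which left that median at 0.028, the precursor median was 0.52, with 85 higher and 4 lower. The calls of NAC1, TIR1, DCL3 and AT2TU062680 ended when single arrays were left out, with limma's adjusted p between 0.0536 and 0.139.

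**Figure D1:**
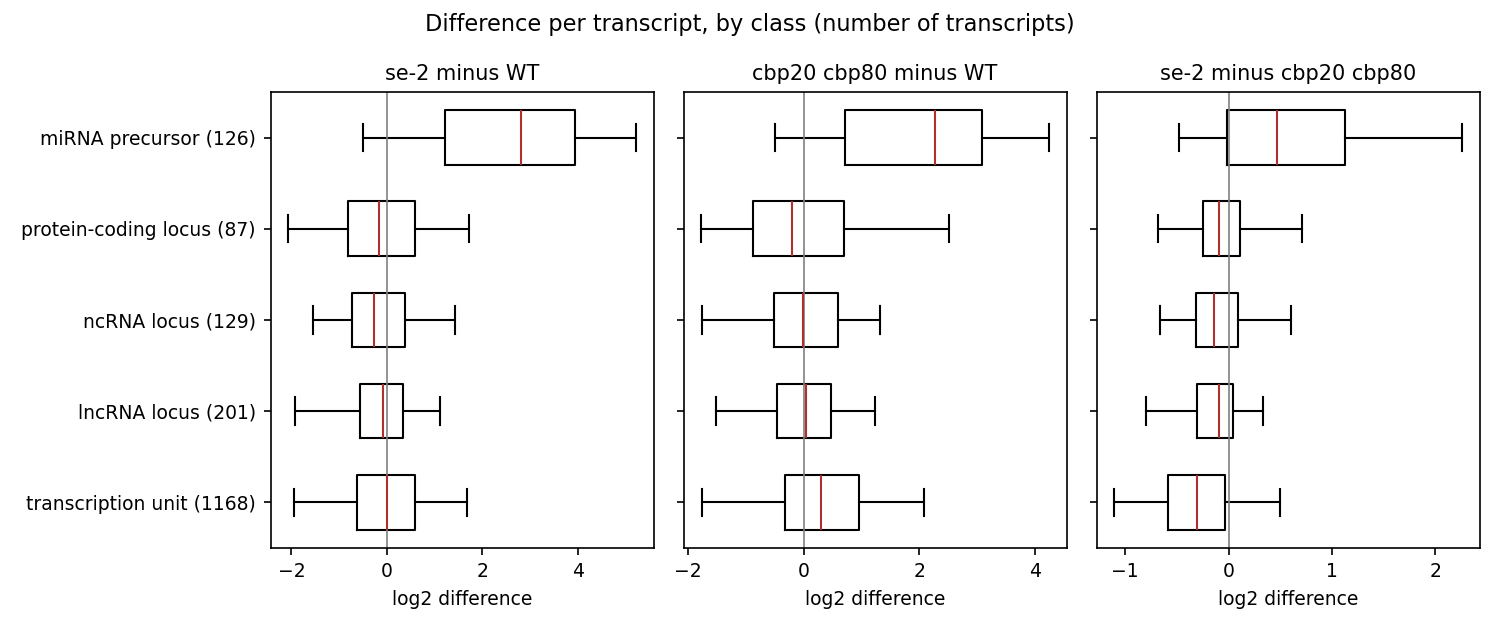
Log2 difference of the tested transcripts (x axis, whose range differs between panels) by transcript class (y axis), for each mutant minus WT and for se-2 minus cbp20 cbp80, with boxes at the quartiles, the median in red and whiskers from the 5th to the 95th percentile. The miRNA precursors lie above the other classes, with medians of 2.81 in se-2 and 2.28 in cbp20 cbp80, which under normexp background correction were 0.16 and 0.14, or -0.0081 and -0.039 by probe, and 0.77 and 0.52 with quantile normalization after it, while the median of 0.46 between the mutants became -0.033 and 0.24.

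Both mutants shared most of their differences from WT. Of the probes tested, 532 were higher in both and 435 lower in both, 967 in all, while 5 were called in opposite directions, 3 of these with a genotype that was not well above background on any array. Ranked by the smaller of a transcript's changes in the mutants, the first 5 that rose in both were MIR156c, MIR156a, MIR156d, AT5TU075750 and CCA1, and the first 5 that fell were AT5TU077800, AT2G41178, AT3TU029400, AT5TU022680 and AT4TU028510. This order used fitted changes, and some of these have only bounds: MIR156d was well above background on 2 WT arrays, AT5TU075750 on none, AT5TU077800 on no cbp20 cbp80 array, and the other 4 that fell on no mutant array. The calls of CCA1 and of these 4 ended with the slide as a block in both mutants. Independent lists of these sizes would share 150.4 higher and 106.0 lower probes. The log2 changes correlated with r = 0.887 across probes, which are not independent replicates, and 86.2% had the same sign.

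Both comparisons use the same WT arrays. With unchanged genotypes and independent arrays, simulation gave r = 0.500, a covariance of 0.0727 against 1.65 observed, the same sign for 66.7% and no shared calls. With slides differing as much as the WT slides did, it gave r = 0.977, a covariance of 0.902, the same sign for 92.7% and 572 shared calls, between 471 and 646. The covariance exceeded these values by 1.58 and 0.747. The 3 WT arrays cannot be split into parts of at least 2, so the shared controls were allowed for by simulation alone. Both simulations share the WT arrays, so the excess is what their simulated spread leaves. The simulated slides differed only as much as the WT slides did. A larger difference special to the slide of the mutants was not simulated and may give part or all of the excess. With the slide as a block, 150 probes were called the same way in both mutants. The F-test over the 3 genotypes called 1374 probes by limma.

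**Figure D2:**
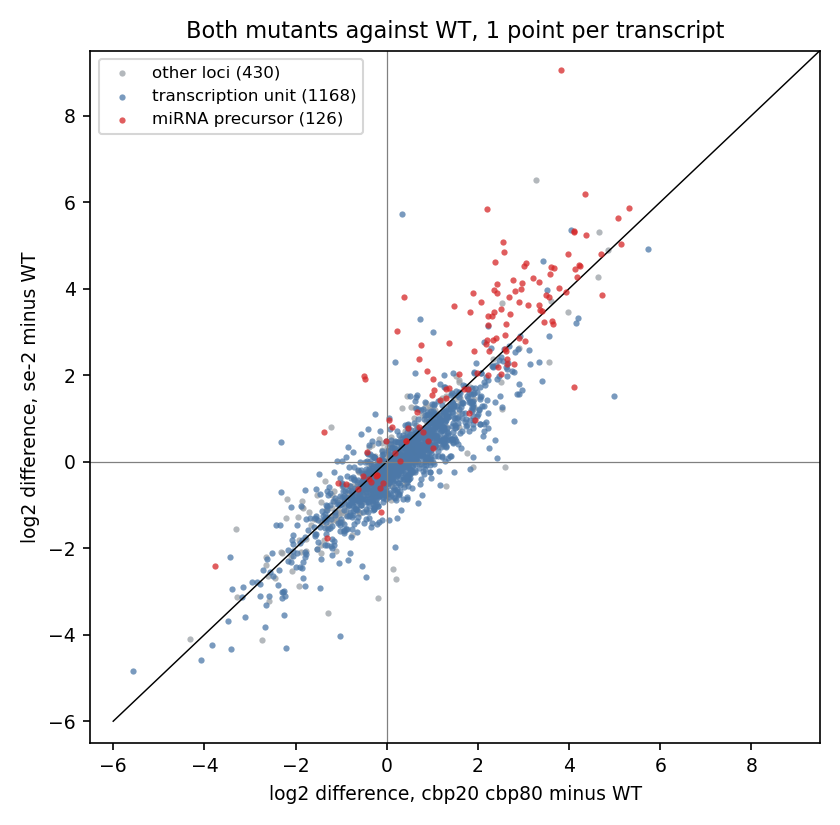
Log2 difference from WT in se-2 (y axis) against that in cbp20 cbp80 (x axis), with 1 point per tested transcript coloured by class and a line where both are equal. Across probes r was 0.887, beside 0.977 in simulations of unchanged genotypes on slides that differ as the WT slides did.

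The direct comparison of the mutants addressed where loss of SERRATE and of the cap-binding complex differ, on arrays of 1 slide. Of the miRNA precursors, 28 were higher in se-2, 2 lower and 96 not passing, and within the slide 77 were higher and 17 lower. Under normexp, which moved the median of all probes to -0.44, over 9 arrays 43 were higher and 34 lower with a median of -0.033, and within the slide 83 precursor probes were higher and 111 lower, against 134 and 31. With quantile normalization after normexp 52 were higher and 2 lower over 9 arrays, with a median of 0.24. MIR172b was 5.22 ± 0.40 higher in se-2 than in cbp20 cbp80 (SE, n = 3), or 37.2-fold, and MIR319a, whose miRNA targets TCP transcription factor genes, was 3.64 ± 0.45 higher, or 12.5-fold. These errors pool the WT spread, and within the slide the SE was 0.060 for MIR172b and 0.058 for MIR319a. MIR166a and MIR166b, whose miRNA targets HD-ZIP III genes, were 1.69 ± 0.13 and 2.26 ± 0.16 higher. MIR779 was 3.41 ± 0.58 higher, while MIR156c (0.56 ± 0.17) and MIR156d (-0.11 ± 0.19) did not pass over 9 arrays. Within the slide MIR156c passed, with an adjusted p of 0.000805 by limma, and MIR156d did not, with one of 0.0905.

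On the list of MIR genes, 12 of 37 transcripts were higher in se-2 and 25 did not pass, and within the slide limma called 32 higher and 0 lower (1 lower at an unadjusted p under 0.05). Of the 66 probes 21 were higher over all probes tested, 31 when adjusted over the list alone and 57 within the slide. The adjusted p of camera was 7.01e-30 for the list and 3.4e-28 for the class, and 0.000377 and 0.00221 with an estimated correlation, so both calls held. Other members that were higher in se-2 were MIR172a (2.52 ± 0.28), MIR390b (1.83 ± 0.27), MIR171c (1.18 ± 0.15) and MIR168a (0.86 ± 0.14).

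Outside the precursors, AT3G29644 was lower in se-2 than in cbp20 cbp80, with log2 differences of -2.95 ± 0.14 for AT3G29644.2 and -2.92 ± 0.15 for AT3G29644.1. DCL1 was 0.71 ± 0.14 higher in se-2, with an adjusted p of 0.0289 by limma and 0.000152 within the slide, and its 3 probes were higher over all probes tested, when adjusted over the list alone and within the slide. EM1 was 3.24 ± 0.58 higher in se-2. AT1TU090130 was at least 26.4-fold higher in se-2 and not well above background in cbp20 cbp80. AT5TU035150 (-3.46 ± 0.64) and AT5TU071970 (at least 7.02-fold, well above background on 1 se-2 array) were lower in se-2. Of the 18 small RNA silencing probes limma called 0 over all probes tested or when adjusted over the list alone (3 at an unadjusted p under 0.05), while within the slide 11 were higher in se-2 and 1 lower. Camera gave that list an adjusted p of 0.000189, which became 0.0891 with an estimated correlation. Of the 10 abscisic acid and cold probes limma called 0 over all probes tested or when adjusted over the list alone (1 at an unadjusted p under 0.05), while within the slide 4 were higher and 4 lower. Of the 5 probes of TIR1 and NAC1 limma called 0 over all probes tested, when adjusted over the list alone, within the slide or at an unadjusted p under 0.05. Of the 2 probes of AT3G25795 limma called 0 over all probes tested (2 at an unadjusted p under 0.05), and both were higher in se-2 when adjusted over the list alone and within the slide. Of the 1168 transcription units 16 were higher in se-2 and 36 lower, and within the slide 63 were higher and 441 lower. Their camera adjusted p of 0.000281 became 0.11 with an estimated correlation. Of the lncRNA loci 2 were higher in se-2 and 4 lower, and within the slide 18 were higher and 62 lower.

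In all, 192 probes differed between the mutants by limma with Benjamini-Hochberg adjustment, 101 higher and 91 lower in se-2, and all were among the 1482 that differed within the slide, 421 higher and 1061 lower. The within-slide calls rest on a small spread. Over probes well above background on all arrays, the median SD between arrays was 0.0557 in se-2 and 0.0657 in cbp20 cbp80. Replicate spots of the E1A spike-in control probes within an array had a median SD of 0.0455 to 0.139. A mutant's arrays thus differed about as little as repeated spots, and how far these calls extend to other plants was not tested. Leaving out any 1 of the 9 arrays moved the count of 192 by over 1.5 times, to between 64 (without se-2 replicate 1) and 545 (without WT replicate 3), and that of 52 precursor probes higher to between 30 and 85 without the same arrays. The split over 9 arrays became 116 higher and 53 lower with median scaling, 113 and 42 with quantile normalization, 166 and 36 with the percentile over all probes, 124 and 1924 with normexp, 160 and 62 with normexp and quantile normalization, and 112 and 38 with the authors' value table. Within the slide it became 694 and 631 with median scaling, 713 and 526 with quantile normalization, 1060 and 282 with the percentile over all probes, 246 and 2507 with normexp and 730 and 438 with the value table. Transcription units thus had no direction that held across scalings, with 275 higher and 281 lower within the slide after quantile normalization. The precursor probes had a median of 0.46, or -0.087 under normexp, and stayed above the transcription units by 0.725 and 0.428. Over 9 arrays the calls of DCL1, EM1, AT5TU035150, MIR168a and MIR779 ended when any 1 mutant array was left out, with limma's adjusted p between 0.0502 and 0.144, and within the slide all of them passed.

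**Figure D3:**
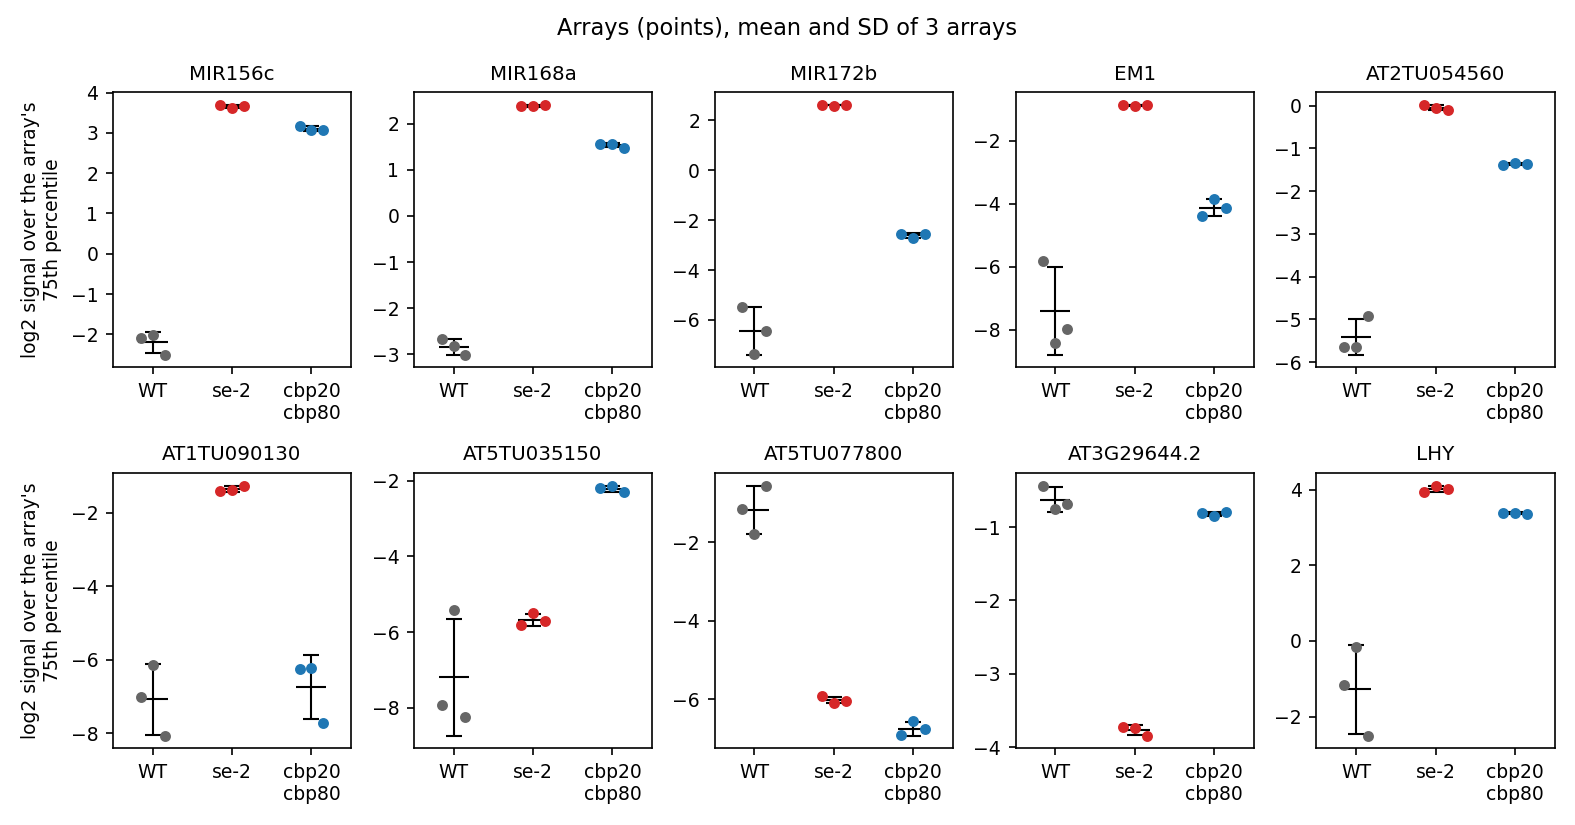
Scaled log2 signal (y axis, whose range differs between panels) of 10 transcripts on each array (points) by genotype (x axis), with the mean and SD of the 3 arrays. MIR172b lay at 2.61 in se-2 and -2.61 in cbp20 cbp80 and was not well above background on any WT array, whose points are background levels, and LHY had an SD of 1.17 among WT arrays.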

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

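The tests of slide differences, of probes bright only in a mutant, of harvest time and of the spike-in spread were chosen after the results were seen, as were the scalings of the precursor tests and the splits that keep a slide together, and that of harvest time was computed first over all 7 clock genes and then without the 2 that prompted it; the counts over other splits of the arrays were planned.

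The probes called in opposite directions against WT, 5 in all, were looked at again for that reason. The difference between the mutants there is the sum of both called changes, so its passing over 9 arrays adds no support, and its passing within the slide is not independent of the choice either. At the brightest probe none of these transcripts was called in opposite directions. Log2 differences are given as se-2 minus cbp20 cbp80. MIR169b had a fitted difference of -2.10 at a probe well above background on 0 WT arrays and 2 se-2 arrays. As se-2 was partly dim there, this value is not a bound and may overstate the difference. Its brighter probe, at 0.97 in se-2 (not passing) and 1.93 in cbp20 cbp80, differed by -0.96, which passed within the slide alone (limma's adjusted p 0.00358, against 0.202 over 9 arrays). AT5TU059430 differed by -1.69, and its brighter probe by -1.79. AT3G29644.1 differed by -2.82 at this probe and by -2.92 at its brightest. AT1TU090130 differed by 4.16 at this probe, which was not well above background in cbp20 cbp80, so se-2 was at least 9.99-fold higher there and at least 26.4-fold higher at its brightest probe. AT2TU046340 had a fitted difference of 1.38 at this probe, but WT and cbp20 cbp80 were not well above background there, so its lower call in cbp20 cbp80 compared groups at background and the bounds allowed no difference between the mutants. None of the calls of cbp20 cbp80 against WT at these 5 probes held with the slide as a block, with limma's adjusted p between 0.127 and 0.765.

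The miRNA precursors were higher in both mutants than in WT, relative to the transcription units on the same array, by 2.77 in se-2 and 1.85 in cbp20 cbp80, or 1.01 and 0.478 under normexp. The smaller shift, 1.85, was 5.83 times the range of 0.318 over the 3 WT slides, and 4.75 to 10.8 times under the other scalings. Slide differences of the size seen among these 3 slides were thus too small to be the whole cause. A range over 3 slides does not bound what a further slide can do, so larger slide differences were not excluded. Testing of probes that are bright only in a mutant was not excluded under every scaling: the 65 precursors well above background on all WT arrays had median changes of 2.04 in se-2 and 1.70 in cbp20 cbp80, but 1.09 and 0.64 under normexp, short of the change of 1 in both that would exclude it. A difference special to the slide of the mutants cannot be told apart from the genotypes for the shift of 1.85, because 0 slides held both WT and mutant arrays. A shift common to that slide cannot give the excess of se-2 over cbp20 cbp80, because both mutants lay on it. Within the slide the difference was 0.919 against a range of at most 0.134 among arrays of a genotype (3.87 to 12.7 times that range over the scalings). A mutant's arrays differed about as little as repeated spots, so that range does not cover handling that differed by genotype. The arrays' 75th percentile was 501 to 531 in se-2 and 325 to 342 in cbp20 cbp80, and such handling was not tested. Loss of SERRATE or of the cap-binding complex may account for both parts, as a hypothesis found and tested on the same data.

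Clock genes differed from WT in both mutants: CCA1 (4.89 and 4.86), LHY (5.31 and 4.66) and PRR9 (3.46 and 3.97) were higher, TOC1 (-1.37 and -1.39) and PRR3 (-1.32 and -1.60) were lower, and PRR7 (1.44 and 1.91) and PRR5 (0.80 and 1.33) did not pass. Without CCA1 and LHY, which prompted the test, the mean changes of the other 5 genes had a Spearman's rho of -0.900 with the order of their daily peaks, which did not pass (exact permutation test, two-sided p = 0.0833), and clock genes regulate each other, so they are not independent. Plants harvested at a different time of day are a candidate explanation, and an effect of the mutations on the clock might give the same changes. These cannot be told apart, because no label gives a time of harvest and the WT arrays covered all mutant arrays for 2 of the 7 genes, PRR7 and PRR5, and none of them for the other 5. The WT arrays varied by 4.18 for CCA1 and 3.86 for PRR9, with the slide as a block LHY alone passed, and with the percentile over all probes TOC1 and PRR3 did not pass in se-2 while PRR7 passed in both mutants (2.39 and 2.51), as PRR7 did in cbp20 cbp80 with quantile normalization, the value table and both forms of normexp, and PRR5 (1.48) with normexp.

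The WT arrays varied more than the mutant arrays, with a median SD of 0.544 against 0.0856 in se-2 and 0.108 in cbp20 cbp80. Labelling, hybridisation or scanning that differed between slides may contribute: the level of the E1A spike-in probes, scaled by each array's 75th percentile, had a median SD of 0.707 among WT arrays, 19.4 times the larger SD of 0.0364 among a mutant's arrays. That percentile is taken over plant probes and was 180, 369 and 236 on the WT arrays. The scaled level thus moves with the plant signal too and is not a measure of the slides alone. The clock genes, picked after the data were seen, had WT SDs at a median percentile of 95.8 among tested probes, from 24.3 (TOC1) to 98.9 (CCA1). For CCA1, LHY, PRR9, PRR7 and PRR5, WT replicate 2 was highest and WT replicate 3 lowest. For PRR3 and TOC1, WT replicate 1 was highest. A difference between the WT plants may therefore contribute too. How much of the spread between WT plants is biological was not tested.

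Among the 10 splits of 6 arrays, too few for a share under 0.05, the real split called 1273 probes for se-2 against WT, 1255 for cbp20 cbp80 against WT and 192 between the mutants, and the highest of the other splits called 0 in each. For the 3 genotypes, 1 of 100 splits drawn from 280, the real one, called as many as 1374 probes, and the highest other called 860. That share would exclude chance only for exchangeable arrays, and 6 of the 9 shared a slide (consensus correlation 0.948); the splits that keep this slide together number 10, too few for a share under 0.05, and the highest other among them called 860.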

How the results depend on the processing

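Array weights per genotype and the within-slide fits under other scalings were chosen after the data were seen. Counts are given in the order se-2 against WT, cbp20 cbp80 against WT, se-2 against cbp20 cbp80, called the same way in both mutants, and differing among the 3 genotypes, against 1273, 1255, 192, 967 and 1374; precursor probes higher were 167, 145 and 52, and transcription unit (TU) probes changed 605, 633 and 91. Over 31 other settings, 3582 of 4069 values of the named transcripts kept their side of the threshold, and called ones also their direction, while 193 lost the call, 272 gained it and 22 reversed. Where no construction is named, the cause was not tested.

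Scaling shifted the median of all tested probes from 0.0024, 0.17 and -0.15 in the 3 comparisons to 0.95, 0.77 and 0.20 with the percentile over all probes, -0.77, -0.31 and -0.44 with normexp, 0.19, 0.11 and 0.064 with quantile normalization, and -0.094, -0.078 and 0.0013 with median scaling. Quantile normalization moved r to 0.909 and TU probes between mutants to 54, and the authors' value table moved them to 0.909 and 52. The percentile over all probes gave 1939 for se-2, 1499 the same way and 973 TU probes in se-2. Normexp gave 2568, 1915, 2048, 1777 and 2622 probes, 84 and 78 precursor probes higher against WT, and 1541, 1111 and 1414 TU probes. Normexp with quantile normalization gave 93 precursor probes between mutants.

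With the percentile over all probes DCL3 reversed to 0.74 (se-2) and 0.16 (cbp20 cbp80), TIR1 to 0.21 and 0.0076, and RDR2 to 0.71 (se-2). Under normexp, in se-2, NAC1 reversed to -0.62, AT3G25795.1 to -0.34, AT5TU035150 to -0.81 and MIR843 to -0.44. In cbp20 cbp80, NAC1 reversed to -0.17, AT1TU090130 to -0.41, EM1 to -0.095, MIR172a to -0.14 and MIR319a to -0.17. Between the mutants, with 9 arrays and within the slide, AT2G41178.1 reversed to -0.51, AT2TU062680 to -0.48 and AT5TU077800 to -0.43, and within the slide MIR395c to -0.12 and MIR399c to -0.11. By construction, the normexp offset of 50 is added before the scaling, so dim probes follow each array's 75th percentile. For the processed signal, that percentile was higher on every se-2 array than on any other array. With 9 arrays, 12 of 150 named values reversed under normexp, and 0 of 150 with quantile normalization after it. The reversals under normexp were thus tied to the scaling that followed it.

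Without a filter on dim probes, so with 15013 probes tested, se-2 gave 9129, the mutants 58, the same way 1498, the genotypes 6832, r 0.833, TU probes 8337, 1190 and 17, and precursor probes between mutants 26. With the 1835 probes well above background on all arrays, fewer probes gave 751 for cbp20 cbp80, 622 the same way, 887 among genotypes, r 0.906, precursor probes 61, 57 and 26, and TU probes 326 and 259 against WT. With 1 mean per transcript, fewer units gave 623, 684, 98, 487 and 717, precursors 97, 88 and 34, and TU 357, 420 and 45.

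The replicate block lowered the calls between mutants to 100 and TU probes there to 37, and left the other counts within 1.5 times (1154, 1140, 870 and 1222). The numbers did not pair the arrays: the 9 correlations of same-numbered arrays lay between -0.0483 and 0.0318.

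The slide as a block gave 205, 173, 1482 and 150 probes, precursors 100, 81 and 134, and TU 53, 49 and 744. It treats the WT slides' spread as spread between slides. Of named values, 27 lost and 17 gained a call. Array weights gave 797, 824, 1523, 615 and 805, TU 301, 324 and 805, and precursors between mutants 136, and weights per genotype 686, 659, 1546, 515 and 655, TU 248, 240 and 813, and precursors 136. Only the 6 arrays of a comparison gave 417 TU probes for cbp20 cbp80 and, between mutants, 1482 probes, 134 precursor and 744 TU probes. Within the slide, calls between mutants, precursors and TU probes were 1325, 149 and 597 with median scaling, 1239, 156 and 556 with quantile normalization, 1342, 172 and 517 with the percentile over all probes, 2753, 83 (with 111 lower, against 31) and 1641 with normexp, and 1168, 158 and 528 with the value table. At least 2-fold left 60 TU probes between mutants. An adjusted p under 0.01, a stricter threshold by construction, left 802, 767 and 78, TU 358, 358 and 25, and 34 precursors between mutants. The trended prior moved none of these counts by over 1.5 times.

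Leaving out 1 array gave 899 to 1661 for se-2, 930 to 1658 for cbp20 cbp80, 64 to 545 between mutants, 728 to 1320 the same way, 1042 to 1848 among genotypes and r 0.869 to 0.904. Precursor probes ran from 154 to 176, 137 to 156 and 30 to 85, and TU probes from 412 to 849, 460 to 891 and 19 to 309. Only counts between mutants moved by over 1.5 times, and every array did that: without WT replicates 1, 2 and 3 they were 313, 434 and 545 (TU 148, 230 and 309), without se-2 replicates 64, 68 and 80 (TU 19, 22 and 27), and without cbp20 cbp80 replicates 89, 87 and 97 (TU 36, 31 and 42). Precursors there were 85 without WT replicate 3 and 30 without se-2 replicate 1 or 2. By construction, the WT arrays enter the comparison between mutants only through the scaling, the choice of probes tested and the pooled spread. Without WT replicates 1 and 2, r was 0.902 and 0.904, and without cbp20 cbp80 replicates 2 and 3 it was 0.875 and 0.869. In cbp20 cbp80 the call of DCL3 ended without any 1 mutant array (limma's adjusted p 0.0844 to 0.139), NAC1 without WT replicate 1 or any cbp20 cbp80 array (0.0547 to 0.0809), TIR1 without any se-2 array or cbp20 cbp80 replicate 1 or 2 (0.0536 to 0.113) and AT2TU062680 without cbp20 cbp80 replicate 1 or 2 (0.0653 to 0.0654). In se-2, TIR1 ended without se-2 replicate 3 (0.059). Between the mutants, DCL1, EM1, AT5TU035150, AT5TU075750, MIR168a, MIR413 and MIR779 ended without any 1 mutant array (0.0502 to 0.165), AT5TU071970 without se-2 replicate 1 or 2 (0.0625 to 0.073) and AT2TU054560 without these or cbp20 cbp80 replicate 3 (0.0511 to 0.0629). No called value changed sign when 1 array was left out, which leaves 2 arrays in that genotype and a spread pooled over genotypes. Signal over background limits the rest: 9107 probes were well above background on no array and could not be compared.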

Other observations

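The grouping of precursors by family age and the transcripts named here were chosen after their values were seen.

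Precursors of families known from many land plants, such as MIR156, MIR166 and MIR172, had larger median changes than the other precursors, which describes them and tests nothing: permutation p-values were computed and are not used here, since the grouping was chosen after the values were seen and precursors of a family are related. Of 83 tested precursors of such families, 75 were higher in se-2 and 0 lower, with a median log2 change of 3.60, and 75 were higher in cbp20 cbp80 and 0 lower, with a median of 2.61. Of the 43 others, 21 were higher and 4 lower in se-2, with a median of 0.96, and 13 were higher and 4 lower in cbp20 cbp80, with a median of 0.43. Under normexp background correction the families' medians stayed positive at 0.99 and 0.50, with 16 precursors lower in se-2 and 6 in cbp20 cbp80, and those of the others turned to -0.55 and -0.28, while with quantile normalization after normexp the others stood at 0.16 and 0.066. The medians differed by 2.64 and 2.18. Between the mutants the medians were 0.66 and 0.030 (0.22 and -0.31 under normexp, 0.39 and 0.075 with quantile normalization after it). Families also differed in the excess of se-2 over cbp20 cbp80, with a median of 2.52 over 3 MIR172 precursors, which ran from 0.47 to 5.22, and 1.55 over 6 of MIR166, against 0.11 over 7 of MIR156 and 0.29 over 3 of MIR398. Under normexp these medians were 1.14, 1.28, -0.14 and 0.30, so the order of MIR172 and MIR166 turned, and these differences between families were not tested.

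Among protein-coding loci, PAD3, an enzyme gene of camalexin synthesis, fell by 3.22 in se-2 and by 2.57 in cbp20 cbp80, with limma's adjusted p of 0.00746 and 0.0242 with the slide as a block. WRKY40, a transcription factor gene of defence, fell by 3.51 in se-2 (0.0402 with the slide as a block) and stood at -1.29 ± 0.54 in cbp20 cbp80, without passing, and within the slide the mutants differed by -2.22 (adjusted p 6.37e-06 by limma), which did not pass over 9 arrays (0.0512). HFR1, a gene of light signalling, rose by 2.59 ± 0.32 in cbp20 cbp80 and stood at -0.13 in se-2 (0.82 with the percentile over all probes), and the mutants differed by -2.72 ± 0.32. AGO2 was 1.51 ± 0.33 higher in se-2, with an adjusted p of 0.00759 by limma and 0.196 with the slide as a block, and was 1.06 higher than in cbp20 cbp80 (limma's adjusted p 7.92e-05 within the slide, and 0.121 over 9 arrays, where it did not pass). FHL fell by 2.08 in se-2 (0.039 with the slide as a block) and was -1.88 ± 0.22 in cbp20 cbp80 (0.0682). The jasmonate repressor genes JAZ5 (-2.11 ± 0.66 and -2.29 ± 0.66) and JAZ10 (-1.38 ± 0.39 and -1.44 ± 0.39) were lower in both mutants by limma over 9 arrays and did not pass with the slide as a block or with the percentile over all probes. MIR846 went 2 ways by probe: its brightest probe was -1.17 ± 0.16 in se-2, and its other probes were higher in se-2, by at least 2.37-fold at one not well above background in WT, and at one well above background on 1 WT array.

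The 9 promoter probes of the array were well above background on no array, and their highest signal was 4.05.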
